A study of Homo sapiens with 9 samples.

How the data were processed

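Gene expression had been measured on 9 Affymetrix whole-genome arrays. A pair of arrays held hepatocytes derived from induced pluripotent stem cells (iHeps) in micropatterned co-culture, at day 9 and day 21. The other 7 held primary human liver cells: freshly isolated hepatocytes of 2 donors, a fresh mixture of liver cells of donor 1, hepatocytes in micropatterned co-culture at days 6, 18 and 42, and hepatocytes in randomly seeded pure culture at day 6. The supporting cells of the co-cultures are not named in the labels. As background, such co-cultures are usually built with mouse fibroblasts. Groups, days and donors were read from the sample titles. For the day 42 array the title and the individual tag name different donors, so its donor was left open and was not sought in the data.

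Per the labels' protocols, RNA of iHeps and of primary hepatocytes was extracted in different ways (column kit with DNase for iHeps, phenol-based extraction and a column for primary cells) and labelled with different kits. Cell source and protocol therefore could not be separated in any comparison of iHeps with primary hepatocytes. The deposited table holds 1 intensity per probe set and array on a linear scale, read from its positive values with a long right tail. The method by which the authors summarised probes and scaled the arrays was not given in the sources used here. All 9 columns were mapped to samples (0 unmapped), and 0 pairs of arrays were identical.

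Values were transformed as log2 of intensity plus 16, which damps noise near background and understates changes of dim genes. Where 1 group lay near or below an intensity of 16, the log2 difference depends on this constant, which damps its size. Very bright probe sets may be compressed, since the upper limit of the signal was not given. Array medians lay between 14.35 and 17.08 on the intensity scale and spanned 0.12 on the log2 scale, under the limit of 0.5 above which quantile normalization would have been used, so the arrays were not scaled again. No detection calls were available. Of 54675 probe sets, 42898 carried a gene in the platform's annotation and 11777 did not; 1801 named several genes and were left out, as were the 62 control probe sets. Of 41097 probe sets with a single symbol, 41043 were matched to current symbols by gene identifier (0 symbols changed). Sex-linked genes, HLA genes and genes with common deletion or null genotypes, 134 probe sets in all, were left out for the donors' privacy. A further 6 with a single symbol were among the control probe sets, which left 40957. Each gene was represented by the probe set with the highest mean log2 value, giving 19708 genes, and 16588 genes above the 40th percentile of the array on at least 2 of the 9 arrays were tested.

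The tests used R 4.3.3 with limma 3.58.1 (lmFit, eBayes), and the figures Python 3.11.15 with matplotlib 3.10.9. One fit held 8 arrays with a mean each for iHeps in co-culture (2 arrays), primary hepatocytes in co-culture (3), fresh hepatocytes (2) and pure culture (1). The fit had 4 residual degrees of freedom and 7.20 after moderation. Arrays of different days and donors counted as replicates of a culture system, so the spread includes day and donor, and the lone pure-culture array was assumed to vary like the others. The 2 iHep arrays were told apart only by day, with no donor read from their labels. Their p-values may therefore not cover a spread between cell lines. Contrasts were iHeps against primary co-culture, iHeps against fresh hepatocytes, primary co-culture against fresh hepatocytes, and pure culture against primary co-culture. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Errors after ± are standard errors of log2 differences, or standard deviations (SD) where named. The p-values measure only the spread between these samples.

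A set of 32 gene lists was tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The lists were drug-metabolising cytochromes, conjugating enzymes, hepatic transporters, bile acid genes, urea cycle and amino acid catabolism, gluconeogenesis and glycogen, plasma proteins, coagulation, complement, acute phase, liver transcription factors, fetal liver genes, pluripotency, cholangiocyte, intestinal, mesenchymal, endothelial, macrophage, lymphocyte and erythroid markers, proliferation, immediate early and stress genes, inflammation, interferon response, cholesterol synthesis, lipogenesis, fatty acid oxidation, glycolysis and hypoxia, oxidative phosphorylation, cytoskeleton and dedifferentiation, metallothioneins, and ribosomal proteins. Members past the threshold were counted after adjustment over all genes and adjusted over the list alone. Pairs of single arrays (iHep day 21 and day 9, primary co-culture day 18 and day 6, pure culture and co-culture at day 6, fresh mixture and fresh hepatocytes of donor 1) had no replicates. They are described by genes with at least 2-fold differences and by the percentile of a list's median among 10000 random lists of the same size, matched on mean level in 20 bins.

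Genes named are the 6 largest called changes in each direction (5 largest differences for single arrays), the 2 largest called members of each list (or the largest member, as a value, where none was called), and a fixed panel: ALB, AFP, CYP1A2, CYP3A4, CYP7A1, SLC10A1 and ASGR1. CYP3A7 and HNF4A, also in the panel, were not analysed here because no probe set was annotated to either of them alone. Probe sets of close gene families (CYP2A6 and CYP2A7, UGT2B, MT1) may detect more than 1 member. The groups, contrasts, lists, filter, pseudocount, naming rule and all but 1 of the alternatives were fixed before the data were examined.

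Alternatives were quantile normalization, centring on array medians, no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, pseudocounts of 1 and 64, eBayes with trend and robust options, a fit of only the groups compared, leaving out each array in turn, and donor as a block under either label of the day 42 array. An alternative without the day 18 and day 42 co-culture arrays was added after the data had been seen. Donor pairing came from the labels, and no expression check of it was made because the labels of 1 array conflict. No group reached the size needed for a test of other splits of the samples or of outlying arrays.

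The method was tested on simulated data with the spread of these arrays (16588 genes, 200 of them changed). A true log2 change of 1 was found for 14.7% of changed genes for iHeps against co-culture and for 1.47% for pure culture against co-culture. A change of 2 was found for 86.4%, 78.8%, 83.3% and 57.6% in the 4 comparisons in the order above, and of the genes called 6.47%, 7.46%, 3.85% and 6.54% were false. Precision is limited by the number of arrays, and in the simulation smaller changes were mostly missed. Only 200 genes were changed there, whereas 3265 and 4558 were called for iHeps against co-culture and fresh hepatocytes. The simulated shares therefore do not measure how many changes of a given size were found in those comparisons. The simulated noise was independent between genes and arrays, from a single run per comparison. The false shares therefore may not hold for these arrays, some of which share a donor or differ in day and protocol.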

Results

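Across all 16588 tested genes, the iHep arrays correlated more with the primary co-cultures than with fresh hepatocytes, but among the 180 genes of the lists from cytochromes to complement this held only for the day 42 co-culture. Over all genes the Spearman correlation of the iHep arrays (day 9 and day 21) was 0.813 and 0.837 with primary co-culture at day 42, 0.798 and 0.80 at day 18, and 0.773 and 0.776 at day 6. It was 0.741 and 0.765 with pure culture, 0.722 and 0.728 with fresh hepatocytes of donor 1, and 0.693 and 0.690 with those of donor 2. Over those 180 genes it was 0.774 and 0.808 with co-culture at day 42, 0.642 and 0.658 at day 18, and 0.645 and 0.653 at day 6. With fresh hepatocytes of donor 1 it was 0.707 and 0.719, with those of donor 2 0.656 and 0.674, and with the fresh mixture 0.724 and 0.735. The 2 iHep arrays correlated with each other at 0.967 over all genes. Albumin (ALB), the main plasma protein, had a mean intensity of 7727 in iHeps, 8312 in primary co-culture and 7819 in fresh hepatocytes. The drug-metabolising cytochrome CYP3A4 had 1194, 1184 and 1686. ALB readings may be compressed, as on the day 42 co-culture array, where ALB was at 8775 and the maximum at 9423. Equal ALB levels therefore cannot be read from them with certainty. Other genes differed widely. The fetal plasma protein AFP was at 5509 in iHeps and at 51.6 and 57.6 in the primary groups. The ethanol-oxidising cytochrome CYP2E1 was at 35.3 against 3093 and 6802.

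**Figure D1:**
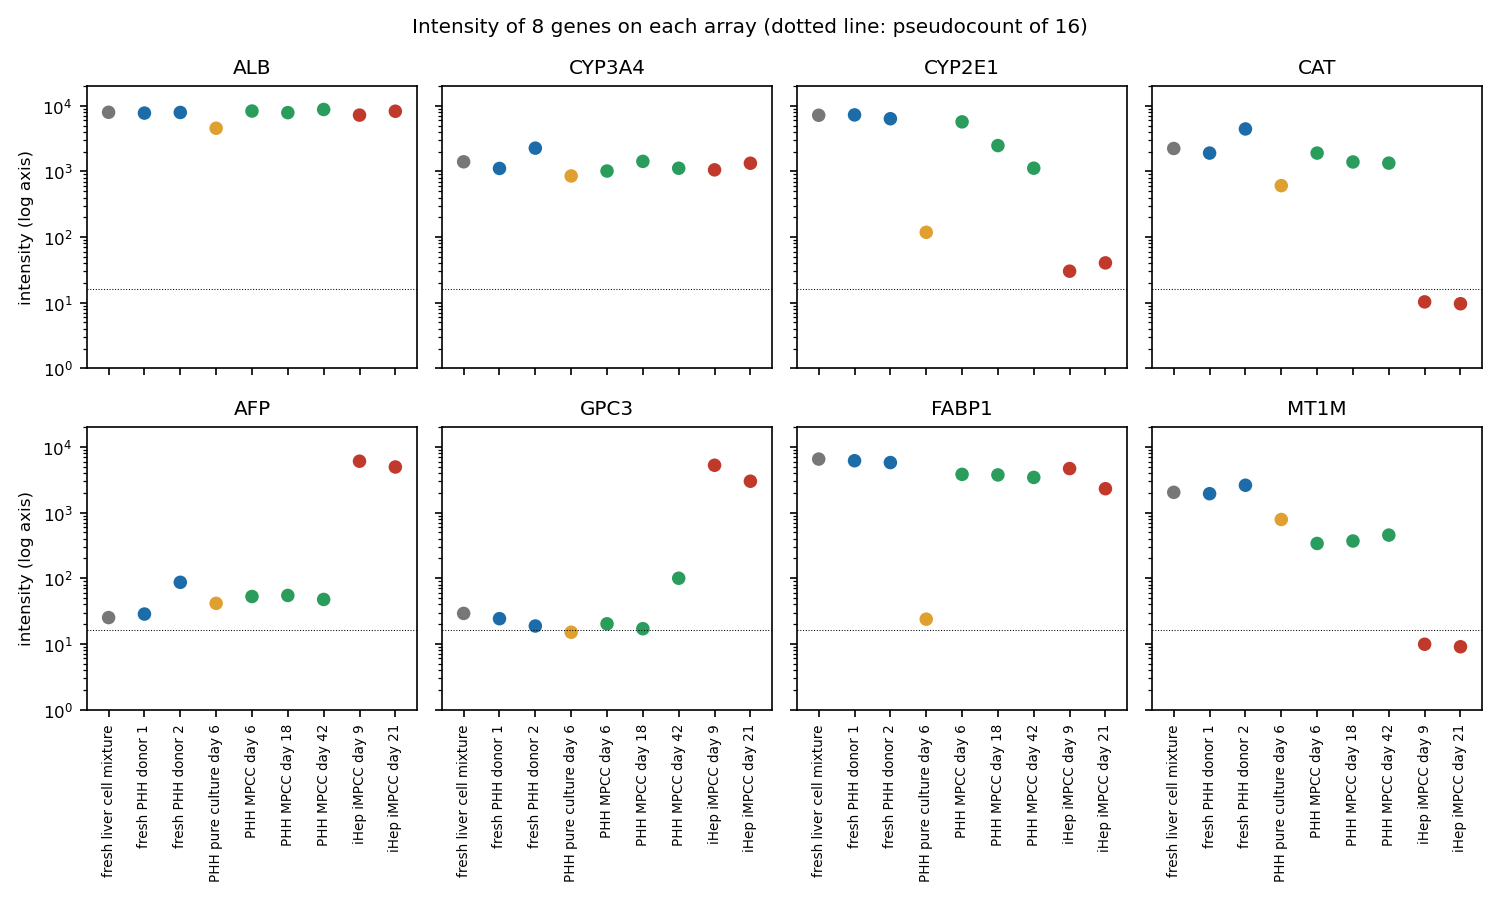
Intensity of 8 genes on each of the 9 arrays, on a log axis. ALB, CYP3A4, CYP2E1, CAT, AFP and GPC3 are shown with FABP1 and MT1M. The dotted line marks an intensity of 16, the constant added before taking logs. Each point is 1 array.

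Compared with primary hepatocytes in co-culture, iHeps had far higher levels of the fetal genes AFP and GPC3 and near-background levels of enzymes such as CAT and ADH4. The largest increases were LYZ (lysozyme, 6.70 ± 0.92 on the log2 scale, adjusted p = 0.0058), DUSP9 (a MAP kinase phosphatase, 6.46 ± 0.49) and AFP (6.35 ± 0.35, adjusted p = 4.94e-04). GPC3 (a cell-surface proteoglycan of fetal liver, 6.27 ± 0.55), PGC (pepsinogen C, 6.00 ± 0.22) and BCAM (a laminin receptor, 5.31 ± 0.51) followed. The largest decreases were THRSP (a regulator of fat synthesis, −6.79 ± 0.52), HSD11B1 (cortisol activation, −6.10 ± 0.40) and CYP2A7 (−5.97 ± 1.29, adjusted p = 0.0212), whose probe set may also detect the near-identical CYP2A6. Next were CAT (catalase, −5.89 ± 0.36, adjusted p = 7.47e-04), CYP2E1 (−5.63 ± 0.59) and ADH4 (alcohol dehydrogenase, −5.57 ± 0.93, adjusted p = 0.0098). THRSP had a mean intensity of 4.04 in iHeps and 2555 in primary co-culture, CYP2A7 2.67 and 1345, and HSD11B1 16.5 and 2379. With readings this near background, the sizes and order of these decreases depend on the constant added before logs, which damps the sizes. In limma, with 2 iHep and 3 co-culture arrays, 2091 genes were higher and 1174 lower in iHeps, 19.7% of those tested. At least 2-fold changes were found for 1625 and 914 of them. The median log2 difference over all genes was 0.08. Without the iHep day 9 array 122 were higher and 41 lower, and without the iHep day 21 array 317 and 131. The counts were 995 and 467 without the co-culture day 18 array.

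Lists of hepatic metabolism fell, although many of their members did not pass the test. Of 14 drug-metabolising cytochromes 0 rose and 5 fell (6 adjusted over the list alone, median −1.43, adjusted p = 1.91e-04), among them CYP2E1 and the fatty acid hydroxylase CYP4F2 (−4.61). Of 19 conjugating enzymes 5 fell (6, with 1 higher, adjusted over the list alone, median −0.79, adjusted p = 0.0071), including NAT2 (arylamine acetylation, −5.08) and GLYATL1 (glycine conjugation, −3.08). Of 18 hepatic transporters 5 fell and 1 rose (8 and 2 adjusted over the list alone, median −1.36, adjusted p = 6.87e-04), with the phospholipid exporter ABCB4 at −3.83 and the uptake carrier SLCO1B1 at −3.01. Of 14 genes of gluconeogenesis and glycogen 9 fell and 1 rose (the same counts adjusted over the list alone, median −2.08, adjusted p = 1.10e-04), such as PPP1R3B (glycogen targeting subunit, −3.03) and UGP2 (UDP-glucose synthesis, −2.97). These 4 list calls were lost when the correlation between members was estimated. The results were adjusted p = 0.901 with an estimated correlation for cytochromes, transporters and gluconeogenesis, and adjusted p = 0.944 with an estimated correlation for conjugating enzymes. Of 26 urea cycle and amino acid genes 7 fell and 1 rose (the same adjusted over the list alone, median −0.72, adjusted p = 9.89e-04), led by BHMT (homocysteine methylation, −5.12) and TAT (tyrosine breakdown, −4.67). Of 19 fatty acid oxidation genes 5 fell and 1 rose (the same adjusted over the list alone, median −0.59, adjusted p = 0.0109), with HADH (−3.79) and EHHADH (−3.58) the largest. Both had adjusted p = 0.957 with an estimated correlation. Without the iHep day 21 array fatty acid oxidation had adjusted p = 0.0788. Of 25 oxidative phosphorylation genes 10 fell (17 adjusted over the list alone, median −0.72, adjusted p = 2.64e-06), such as the ATP synthase subunit ATP5PO (−1.85) and UQCRC2 of complex III (−1.47). All 7 metallothioneins, which bind zinc and copper, fell (7 adjusted over the list alone, median −1.34, adjusted p = 4.65e-06), MT1M by 3.98 on the log2 scale. Probe sets of this family may detect more than 1 member. Both lists had adjusted p = 0.901 with an estimated correlation.

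Of 15 fetal liver genes 9 rose in iHeps and 0 fell (11 and 0 adjusted over the list alone, median 3.19, adjusted p = 2.64e-06). Of 21 ribosomal protein genes 5 fell (5 adjusted over the list alone, median −0.35, adjusted p = 0.025), such as RPL11 (−1.49) and RPS3 (−0.92). Both had adjusted p = 0.721 with an estimated correlation, the lowest of any list. Without the iHep day 21 array the ribosomal list had adjusted p = 0.0617, and with a pseudocount of 1 adjusted p = 0.0703. Of 22 endothelial markers 2 fell (2 adjusted over the list alone, median −1.70, adjusted p = 0.0011, adjusted p = 0.944 with an estimated correlation), MRC1 (a mannose receptor of sinusoidal cells, −2.56) and the clotting factor gene F8 (−1.67). Without the day 18 and day 42 co-culture arrays, an alternative chosen after the data had been seen, the endothelial list had adjusted p = 0.303. Secreted proteins showed no common direction. Of 36 plasma protein genes 7 rose and 4 fell (10 and 6 adjusted over the list alone, median 0.54, adjusted p = 0.832), with IGFBP1 (a growth factor carrier, −4.36) and PON3 (−4.26). Of 23 coagulation genes 3 rose and 1 fell (the same adjusted over the list alone, median −0.05, adjusted p = 0.635), as HRG (a plasma glycoprotein, −3.70) and SERPINF2 (the plasmin inhibitor, 2.58). Of 17 complement genes 2 rose, CFB among them at 1.57, and 2 fell, C4BPB among them at −2.86 (2 and 2 adjusted over the list alone, median 0.08, adjusted p = 0.898). Of 14 acute phase genes 2 rose and 2 fell (the same adjusted over the list alone, median 0.13, adjusted p = 0.973), as LBP (2.10) and CD14 (−2.80), which both bind bacterial endotoxin. For complement, acute phase and erythroid genes the median and mean were above 0 while the test pointed down. ASGR1, a galactose receptor of hepatocytes, rose by 1.32 ± 0.32 (adjusted p = 0.0299). ALB differed by −0.11 ± 0.18 (adjusted p = 0.713) and CYP3A4 by 0.02 ± 0.33 (adjusted p = 0.978). CYP1A2, which oxidises caffeine, differed by −3.23 ± 1.54 (adjusted p = 0.181). CYP7A1, the first enzyme of bile acid synthesis, differed by −1.56 ± 0.83 (adjusted p = 0.221) and the bile acid importer SLC10A1 by −2.05 ± 0.89 (adjusted p = 0.149).

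The remaining lists were not called in this comparison, although single members changed and several lists were called when an array was left out. Of 23 liver transcription factors 8 rose and 0 fell (8 and 1 adjusted over the list alone, median 0.43, adjusted p = 0.0666), led by FOXA3 (4.24) and CEBPD (2.48). Without the iHep day 21 array the transcription factors were called (adjusted p = 0.0235), as they were without the co-culture day 6 array (adjusted p = 0.0241) and with no filter (0.049). Of 13 bile acid genes 2 fell, AKR1C4 (−4.03) and BAAT at −2.43 (2 adjusted over the list alone, median −0.40, adjusted p = 0.0501). This list fell without the iHep day 9 array (adjusted p = 0.0091), without the co-culture day 42 array (median −0.93, adjusted p = 0.0015), without fresh hepatocytes of 1 or the other donor or with only the groups compared (adjusted p = 0.0461), with no filter (0.049), with the mean of all probe sets (0.0402) and with a pseudocount of 1 (0.0492). Of 12 pluripotency genes 2 rose (3, with 1 lower, adjusted over the list alone, median 0.56, adjusted p = 0.138), LIN28B (an RNA-binding protein, 3.19) and SALL4 (2.06), and the list rose with the mean of all probe sets (adjusted p = 0.0185). Of 16 cholangiocyte genes 2 rose, SOX9 (3.36) and CLDN4 at 1.05 (0 adjusted over the list alone, median 0.85, adjusted p = 0.52). Without the co-culture day 42 array cholangiocyte genes rose (median 1.71, adjusted p = 0.0015), as did inflammation (adjusted p = 0.009) and cytoskeleton genes (adjusted p = 0.0143). Of 14 intestinal genes 3 rose and 1 fell (the same adjusted over the list alone, median 0.03, adjusted p = 0.895), as ISX (2.38) and LGALS4 (−4.08). Of 22 mesenchymal genes 3 rose and 1 fell (the same adjusted over the list alone, median 0.32, adjusted p = 0.916), as PDGFRA (1.49) and POSTN (−3.36). Of 19 macrophage genes 1 rose, LYZ, and 1 fell, CD14 (the same adjusted over the list alone, median −0.72, adjusted p = 0.159). In limma 0 of 17 lymphocyte genes (median 0.25, adjusted p = 0.394, CD52 at 0.86) and 0 of 7 erythroid genes (median 0.29, adjusted p = 0.916, SLC4A1 at −0.74) passed. Of 28 proliferation genes 1 fell, MKI67 at −0.99 (1 adjusted over the list alone, median 0.54, adjusted p = 0.199). With the mean of all probe sets MKI67 was at 0.070 (adjusted p = 0.804). The proliferation list rose without the co-culture day 42 array (adjusted p = 3.78e-04) and without the iHep day 9 array (adjusted p = 0.0412). Of 17 immediate early and stress genes 1 rose and 3 fell (the same adjusted over the list alone, median −0.31, adjusted p = 0.228), as DUSP1 (−2.47) and MYC (−1.96). Of 18 inflammation genes 2 rose and 1 fell (the same adjusted over the list alone, median 0.64, adjusted p = 0.325), as VCAM1 (3.81) and IL32 (−1.24). Of 19 interferon response genes 2 rose and 2 fell (2 and 6 adjusted over the list alone, median −0.91, adjusted p = 0.0522), as IFI6 (3.78) and IFIT2 (−2.20). Interferon genes fell as a list without the iHep day 21 array (adjusted p = 0.0304), without fresh hepatocytes of 1 or the other donor or with only the groups compared (0.0075), with no filter (0.049) and with a pseudocount of 1 (0.0289). Of 17 cholesterol synthesis genes 1 fell, the sterol sensor INSIG1 at −1.74 (0 adjusted over the list alone, median 0.43, adjusted p = 0.641). Of 23 lipogenesis genes 2 rose and 3 fell (3 and 3 adjusted over the list alone, median −0.27, adjusted p = 0.582), as PLIN1 (2.17) and GPAM (−2.49). Of 24 glycolysis and hypoxia genes 3 rose and 3 fell (4 and 3 adjusted over the list alone, median −0.13, adjusted p = 0.41), as PFKL (1.41) and PFKP (−2.63). Of 34 cytoskeleton genes 4 rose and 1 fell (the same adjusted over the list alone, median 0.32, adjusted p = 0.635), with ITGA5 (1.79) and ACTN4 (1.73). With the co-culture arrays of day 18 and day 42 both left out, chosen after the data had been seen, bile acid genes fell (median −1.54, adjusted p = 5.20e-04) and lipogenesis genes fell (adjusted p = 0.0266). Cholangiocyte (adjusted p = 0.0017), mesenchymal (0.0266), proliferation (7.19e-04), inflammation (0.0102) and cytoskeleton genes (8.82e-04) then rose.

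Against freshly isolated hepatocytes, the developmental genes GPC3 and OSR1 were higher in iHeps and the metabolic genes CYP2E1 and ADH4 lower. Of 32 lists 17 fell, complement and cytochromes among them, and 3 rose, the fetal, mesenchymal and cytoskeleton lists. For none was the call kept when the correlation was estimated (lowest adjusted p = 0.473 with an estimated correlation). The largest increases were GPC3 (6.74 ± 0.61 on the log2 scale, adjusted p = 0.0015), the developmental transcription factor OSR1 (6.62 ± 0.52) and DUSP9 (6.56 ± 0.54). Next were the chromatin protein HMGA2 (6.46 ± 0.87), AFP (6.35 ± 0.38, adjusted p = 5.23e-04) and the matrix protease MMP14 (6.29 ± 0.78). On the single day 6 arrays of primary cells, HMGA2 was 3.07 higher in co-culture than in pure culture, OSR1 2.56 and MMP14 1.55. CYP2E1 (−7.06 ± 0.65, adjusted p = 0.0015), ADH4 (−6.99 ± 1.02), HSD11B1 (−6.84 ± 0.44), CAT (−6.81 ± 0.40), PON3 (−6.78 ± 0.64) and the lipid transfer inhibitor APOF (−6.50 ± 0.64) fell the most. On the arrays, GPC3 was at 4134 in iHeps and 21.5 in fresh hepatocytes, and APOF at 4.78 and 1981. In limma, with 2 arrays in each group, 2960 genes were higher and 1598 lower (27.5%), around a median of 0.09. At least 2-fold changes were found for 2450 and 1302. Without the iHep day 9 array 805 were higher and 340 lower. The counts were 971 and 411 without the iHep day 21 array, and 1888 were higher without fresh hepatocytes of donor 2. ALB (−0.02 ± 0.20, adjusted p = 0.951), ASGR1 (−0.04 ± 0.35, adjusted p = 0.946), CYP3A4 (−0.41 ± 0.36, adjusted p = 0.428) and CYP7A1 (−0.35 ± 0.91, adjusted p = 0.803) did not pass. Nor did CYP1A2 (−3.19 ± 1.69, adjusted p = 0.199) and SLC10A1 (−2.25 ± 0.98, adjusted p = 0.128).

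Most secreted and metabolic lists fell in iHeps against fresh hepatocytes. Cholesterol synthesis (1 of 17 fell, median 0.17, adjusted p = 0.792), lipogenesis (2 of 23 rose and 2 fell, median −0.50, adjusted p = 0.331) and glycolysis and hypoxia genes (2 of 24 rose and 2 fell, median −0.11, adjusted p = 0.744) did not pass. Of 17 complement genes 8 fell (9 adjusted over the list alone, median −2.40, adjusted p = 1.05e-06), such as C9 of the membrane attack complex (−5.35) and C4BPB (−4.56). Of 14 drug-metabolising cytochromes 9 fell (9 adjusted over the list alone, median −2.68, adjusted p = 1.35e-06), including CYP4F2 (−5.61). Of 14 genes of gluconeogenesis and glycogen 7 fell (7 adjusted over the list alone, median −2.39, adjusted p = 2.87e-06), among them PCK1 (−6.15) and FBP1 (−4.39). Of 18 transporters 9 fell and 1 rose (12 and 1 adjusted over the list alone, median −2.34, adjusted p = 2.05e-06), with ABCB4 (−4.68) and SLCO1B1 (−4.57). Fatty acid oxidation (10 of 19 fell, 15 adjusted over the list alone, median −1.76, adjusted p = 5.12e-07), with EHHADH (−3.80) and HADH (−3.57), moved the same way. Urea cycle and amino acid genes (11 of 26 fell and 1 rose, 12 and 1 adjusted over the list alone, median −1.58, adjusted p = 5.95e-07), with TAT (−5.05) and HPD (tyrosine breakdown, −4.64), and bile acid genes (6 of 13 fell, 7 adjusted over the list alone, median −1.42, adjusted p = 5.66e-04), with AKR1C4 (−4.62) and CYP8B1 (−4.02), fell. CYP8B1 was the brightest probe set on the array of fresh hepatocytes of donor 1 (11029, against 1934 for donor 2), so the size of its difference rests in part on that reading. Each of these 7 called lists had adjusted p = 0.473 with an estimated correlation. Coagulation genes (7 of 23 fell and 1 rose, 13 and 1 adjusted over the list alone, median −1.09, adjusted p = 1.69e-05), with HRG (−4.78) and F11 (−3.44), and conjugating enzymes (7 of 19 fell, 7 adjusted over the list alone, with 1 higher, median −1.06, adjusted p = 2.85e-04), with NAT2 (−5.42) and ACSM5 (−4.55), fell as lists. Acute phase genes (5 of 14 fell, 6 adjusted over the list alone, median −1.02, adjusted p = 8.78e-04), with CD14 (−5.22) and the iron hormone HAMP (−3.91), and plasma proteins (10 of 36 fell and 1 rose, the same adjusted over the list alone, median −0.46, adjusted p = 1.13e-04) fell likewise. Immediate early and stress genes (8 of 17 fell, 10 adjusted over the list alone, median −2.09, adjusted p = 3.27e-05), with the transcription factor FOS (−4.66), and interferon response genes (9 of 19 fell and 1 rose, the same adjusted over the list alone, median −1.43, adjusted p = 1.31e-04), with IFIT1 (−3.61) and IFI44 (−3.15), fell. All 7 metallothioneins (7 adjusted over the list alone, median −1.86, adjusted p = 1.05e-06), with MT1M (−6.48), fell. Each of these 7 called lists had adjusted p = 0.473 with an estimated correlation. Conjugating enzymes had adjusted p = 0.0562 without fresh hepatocytes of donor 2.

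Fetal liver genes rose in 13 of 15 cases (13 adjusted over the list alone, median 4.22, adjusted p = 1.52e-07, adjusted p = 0.473 with an estimated correlation). Of 34 cytoskeleton genes 14 rose and 1 fell (16 and 1 adjusted over the list alone, median 0.98, adjusted p = 0.0018, adjusted p = 0.631 with an estimated correlation), such as the calcium-binding protein S100A6 (4.92) and the tubulin TUBA1A (4.73). Of 22 mesenchymal genes 8 rose (9 adjusted over the list alone, median 1.55, adjusted p = 0.0087, adjusted p = 0.657 with an estimated correlation), with the growth factor receptor PDGFRA at a mean of 2210 against 27.2 and the collagen gene COL3A1 5.44 higher. On the single day 6 arrays of primary cells, PDGFRA was 4.47 and COL3A1 3.56 higher in co-culture than in pure culture. Without fresh hepatocytes of donor 2 the mesenchymal list had adjusted p = 0.0562, and with the mean of all probe sets of a gene adjusted p = 0.0513. Endothelial markers (2 of 22 fell, 2 adjusted over the list alone, median −0.88, adjusted p = 0.0191, adjusted p = 0.657 with an estimated correlation) were lower, as MRC1 (−3.90). Without the iHep day 21 array this list had adjusted p = 0.0606 and without fresh hepatocytes of donor 1 adjusted p = 0.263. Macrophage markers (3 of 19 fell and 1 rose, the same adjusted over the list alone, median −1.86, adjusted p = 4.44e-04) and oxidative phosphorylation (6 of 25 fell, 4 adjusted over the list alone, median −0.36, adjusted p = 8.35e-04) fell, COX5B of complex IV among the latter (−1.20). Each had adjusted p = 0.521 with an estimated correlation. Cholangiocyte genes (adjusted p = 0.118) rose as a list without the co-culture day 42 array (0.0095), with the day 18 and day 42 arrays both left out (0.0178) and with only the groups compared (0.0178). Proliferation genes (adjusted p = 0.102) rose without the iHep day 9 array (0.0209), without the co-culture day 42 array (0.008), with the mean of all probe sets (0.0253), with only the groups compared (0.0107) and with the day 18 and day 42 arrays both left out (0.0107). Pluripotency genes (adjusted p = 0.106) rose with the stricter filter (0.0162) and the mean of all probe sets (0.006), with which liver transcription factors fell (0.0355, against 0.274). Single members of these and other lists changed strongly. The progenitor and biliary gene SOX4 (6.25), the adhesion protein EPCAM (5.12), the chemokines CXCL6 (5.13) and CXCL5 (3.20), LIN28B (3.24), ACLY of fat synthesis (2.56), and TYMS of DNA synthesis (2.10) rose. The nuclear receptor NR1I3 (−4.17), the liver transcription factor CREB3L3 (−3.78) and INSIG1 (−2.57) fell. The lymphoid genes KLRD1 (1.23) and IGHM (1.09) rose from intensities of 4.26 and 10.9 to 31.8 and 41.0. The proliferation marker MKI67 (−1.14) and the lipid droplet protein PLIN5 (−1.87) fell. The direction of these 4 genes turned under another setting, with KLRD1 at −0.14 after quantile normalization and, with the mean of all probe sets, IGHM at −0.39, MKI67 at 0.22 and PLIN5 at 0.14. The median and the mean or the test differed in sign for intestinal, cholesterol synthesis, lipogenesis and glycolysis genes.

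**Figure D2:**
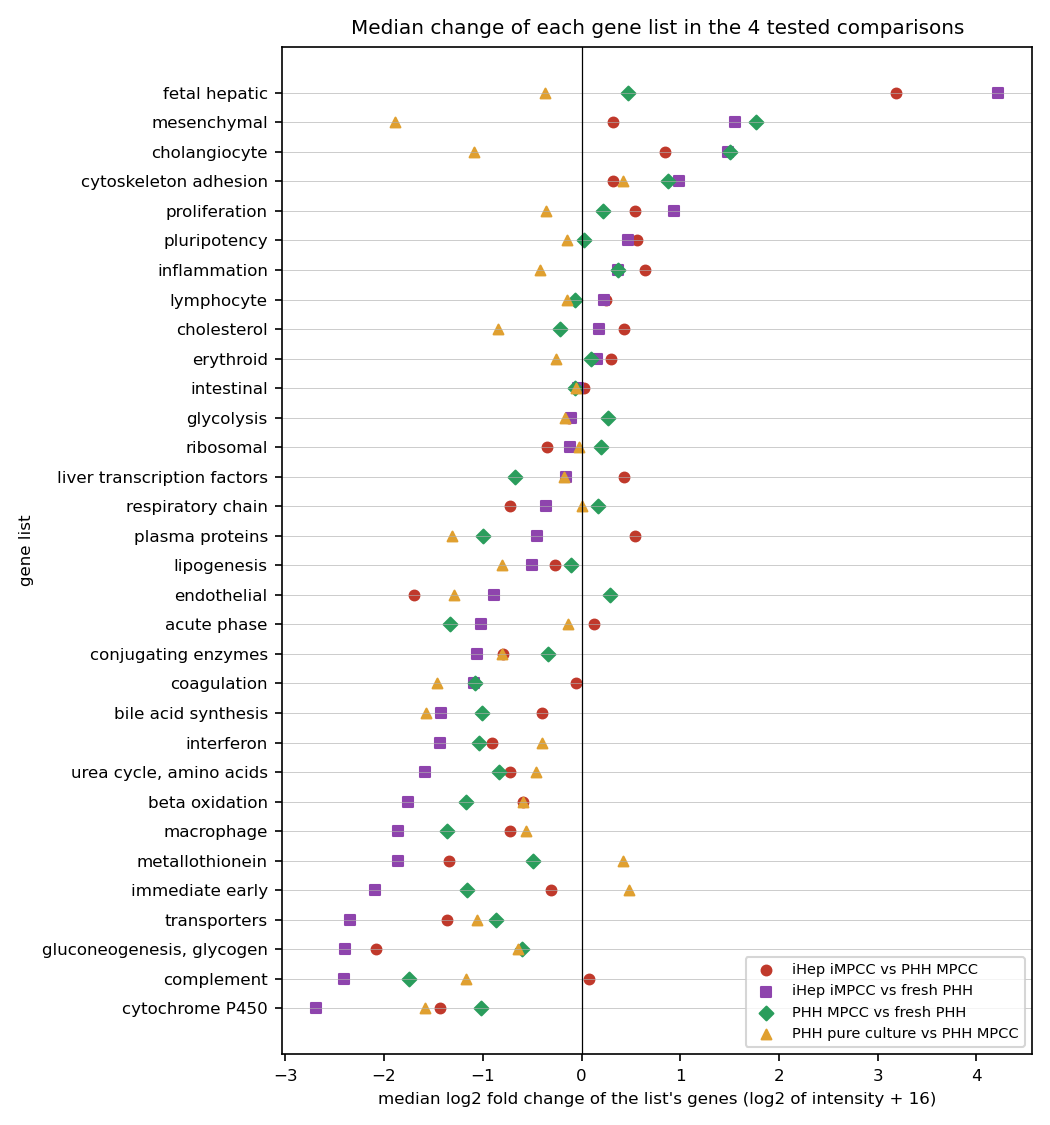
Median log2 difference of the members of each of 32 gene lists in the 4 tested comparisons. Values above 0 are higher in the group named first.

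The arrays of iHeps and of primary cells also differed in a measure of transcript length. The GAPDH 3-prime over 5-prime intensity ratio was 3.38 and 4.52 on the iHep arrays and 0.975 to 1.34 on the primary arrays. The actin ratio was 2.15 and 2.34 against 1.03 to 4.65. This difference, like the extraction and labelling protocols, ran alongside every gene group compared between iHeps and primary cells above, CYP2E1 and AFP included.

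Primary co-cultures had less RNA than fresh cells of CFHR4 and APOF, which encode secreted proteins, and more of the mesenchymal genes LOX and POSTN. The largest decreases were the complement regulator CFHR4 (−4.90 ± 0.74 on the log2 scale, adjusted p = 0.043), APOF (−4.55 ± 0.58, adjusted p = 0.0307), and the acute phase glycoprotein LRG1 (−4.46 ± 0.62). The carboxypeptidase CPN1 (−4.37 ± 0.34, adjusted p = 0.0068), the vasopressin receptor AVPR1A (−4.21 ± 0.22, adjusted p = 0.0033) and the complement pseudogene C3P1 (−4.03 ± 0.52) followed. The largest increases were the motility protein S100A4 (5.59 ± 0.70, adjusted p = 0.0307), the mesenchymal cadherin CDH11 (5.19 ± 0.56), and the aldo-keto reductase AKR1B10 (4.91 ± 0.72). Next were the collagen crosslinker LOX (4.91 ± 0.41, adjusted p = 0.0101), the matrix protein POSTN (4.78 ± 0.71) and DLK1, a member of the fetal liver list (4.55 ± 0.64). On the single day 6 arrays, co-culture exceeded pure culture by 4.88 for S100A4, 3.85 for CDH11, 3.56 for LOX, 3.36 for POSTN and 4.49 for DLK1, but by 0.35 for AKR1B10. Hepatocytes and supporting cells were not measured apart, so these increases cannot be assigned to the hepatocytes. In limma, with 3 co-culture and 2 fresh arrays, 47 genes were higher and 86 lower (0.802%), all at least 2-fold. After quantile normalization 76 were higher and 89 lower. The actin 3-prime over 5-prime ratio was 2.43 on both fresh arrays and 1.84, 1.03 and 1.09 on the co-culture arrays of days 6, 18 and 42, so it moved with CFHR4, LOX and the other genes of this comparison. The count was fragile. It rested in part on the iHep arrays, which enter this comparison only through the shared estimate of the spread. With only the groups compared 5 genes were higher and 11 lower. Without the co-culture day 18 array 0 genes were higher and 1 lower (2070 at an unadjusted p under 0.05 in limma), and without 1 or the other iHep array 5 and 11. The counts were 562 and 276 without the co-culture day 6 array, and 13 were higher without fresh hepatocytes of donor 2. With donor as a block, 18 genes were higher and 27 lower with the donor of the titles, and limma gave 0 and 0 with that of the individual tags (2427 at an unadjusted p under 0.05). ALB (0.09 ± 0.18, adjusted p = 0.837), AFP (adjusted p = 1.00), CYP3A4 (−0.43 ± 0.33, adjusted p = 0.528) and ASGR1 (−1.36 ± 0.32, adjusted p = 0.0966) did not pass.

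By list, complement fell most in primary co-culture: 4 of 17 genes fell (14 adjusted over the list alone, median −1.74, adjusted p = 9.65e-14), including C8B (−3.42) and C8A (−2.77), parts of the membrane attack complex. Of 36 plasma proteins 3 fell (17 adjusted over the list alone, median −0.996, adjusted p = 4.40e-13), such as the inhibitor heavy chain ITIH4 (−3.21). Of 14 acute phase genes 1 fell, HAMP at −3.40 (10 adjusted over the list alone, median −1.33, adjusted p = 8.38e-09). Of 23 liver transcription factors 1 fell, CREB3L3 at −3.99 (4 adjusted over the list alone, median −0.67, adjusted p = 3.24e-08). These 4 lists had adjusted p = 0.363 with an estimated correlation. Coagulation (2 of 23 fell, SERPINF2 at −2.91 and F9 at −1.98, 11 adjusted over the list alone, median −1.08, adjusted p = 2.12e-09, adjusted p = 0.525 with an estimated correlation) fell. Immediate early and stress genes (1 of 17 fell, the heat shock gene HSPA6 at −2.84, 6 adjusted over the list alone, median −1.16, adjusted p = 9.01e-07, adjusted p = 0.533 with an estimated correlation) fell. So did fatty acid oxidation (0 of 19 over all genes, 9 adjusted over the list alone, median −1.17, adjusted p = 4.30e-07), macrophage markers (1 of 19, the haem-degrading HMOX1 at −2.55, 3 adjusted over the list alone, median −1.36, adjusted p = 4.32e-05) and cytochromes (0 of 14, 3 adjusted over the list alone, median −1.02, adjusted p = 1.97e-04). Transporters (0 of 18, 1 adjusted over the list alone, median −0.87, adjusted p = 1.42e-04), interferon genes (1 of 19, IRF7 at −2.57, 2 adjusted over the list alone, median −1.04, adjusted p = 2.68e-04) and metallothioneins (1 of 7, MT1M at −2.50, 1 adjusted over the list alone, median −0.49, adjusted p = 2.68e-04) fell too. These 6 had adjusted p = 0.543 with an estimated correlation. Urea cycle (0 of 26, 0 adjusted over the list alone, median −0.84, adjusted p = 3.00e-05) and bile acid genes (0 of 13, 2 adjusted over the list alone, median −1.01, adjusted p = 0.0062) had adjusted p = 0.573 with an estimated correlation. Gluconeogenesis (1 of 14 fell, the glucokinase regulator GCKR at −1.89, 5 and 1 higher adjusted over the list alone, median −0.60, adjusted p = 0.0081) had adjusted p = 0.641 with an estimated correlation, and conjugating enzymes (0 of 19, 0 adjusted over the list alone, median −0.34, adjusted p = 0.0193) adjusted p = 0.635 with an estimated correlation. Without fresh hepatocytes of donor 2 the calls of cytochromes (adjusted p = 0.618), transporters (0.0615), urea cycle (0.287), bile acid genes (0.395), gluconeogenesis (0.395), conjugating enzymes (0.66, with the test turned upward) and metallothioneins (0.0553) ended. Without the co-culture day 42 array those of bile acid genes (0.225), gluconeogenesis (0.191) and conjugating enzymes (0.191) ended. Conjugating enzymes also had adjusted p = 0.0602 after quantile normalization. With the co-culture arrays of day 18 and day 42 both left out, chosen after the data had been seen, the calls of transporters (adjusted p = 0.161), urea cycle (0.295), bile acid genes (0.79), gluconeogenesis (0.747) and conjugating enzymes (0.574) ended.

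Mesenchymal genes rose in primary co-culture. Of 22 members 3 rose (7, with 1 lower, adjusted over the list alone, median 1.77, adjusted p = 7.19e-05), LOX and POSTN among them. Of 34 cytoskeleton genes 2 rose, S100A6 (4.38) and the tropomyosin TPM1 at 2.23 (8 adjusted over the list alone, median 0.88, adjusted p = 2.60e-05). Of 15 fetal liver genes 1 rose, DLK1 (4 adjusted over the list alone, median 0.47, adjusted p = 0.0208). These 3 lists had adjusted p = 0.543 with an estimated correlation. DLK1 was at 440 in co-culture and 4.26 in pure culture at day 6, so its rise cannot be assigned to the hepatocytes. Ribosomal protein genes rose slightly (0 of 21, 0 adjusted over the list alone, median 0.20, adjusted p = 0.0246, adjusted p = 0.363 with an estimated correlation). With donor of the titles as a block, cholangiocyte genes rose (median 2.05, adjusted p = 9.03e-04, and without a block 1 of 16, SOX4 at 4.32, adjusted p = 0.072). Proliferation genes rose with this block (median 0.37, adjusted p = 0.0319) and ribosomal genes did not pass (adjusted p = 0.0931). With donor of the individual tags as a block, macrophage (median 0.21, adjusted p = 0.215), interferon (adjusted p = 0.538), fetal (adjusted p = 0.117) and ribosomal genes (adjusted p = 0.125) did not pass. Without fresh hepatocytes of donor 1 these 4 did not pass either. Macrophage genes had a median of 0.21 (adjusted p = 0.245), and interferon, fetal and ribosomal genes adjusted p = 0.595, 0.159 and 0.113. Fetal genes also failed without the co-culture day 42 array (adjusted p = 0.0618), with the mean of all probe sets (0.0502) and with a pseudocount of 64 (0.057). Ribosomal genes failed without the day 6 array (adjusted p = 0.0792), with the stricter filter (0.0521) and with a pseudocount of 1 (0.152). With the day 18 and day 42 arrays both left out, cytoskeleton genes had a median of 0.10 (adjusted p = 0.259) and fetal genes adjusted p = 0.149. Cholangiocyte genes rose without the day 6 array (adjusted p = 0.0166) and without the day 18 array (0.0103). Oxidative phosphorylation genes (median 0.17, adjusted p = 0.065) rose without the day 42 array (adjusted p = 0.0146), without the day 18 array (0.0339), with both left out (2.58e-04) and without fresh hepatocytes of donor 2 (0.0272). They also rose after quantile normalization (8.71e-04), with no filter (0.0301), with the mean of all probe sets (0.0256) and with a pseudocount of 64 (0.0155). Cholesterol synthesis genes (median −0.22, adjusted p = 0.118) fell without fresh hepatocytes of donor 2 (adjusted p = 1.81e-04) and without the day 6 array (0.014). Endothelial markers (median 0.29, adjusted p = 0.575) rose without the day 6 array (0.014) and fell with the day 18 and day 42 arrays both left out (0.0048), as did proliferation (0.0334) and inflammation genes (0.0218). Median, mean and test differed in sign for pluripotency, intestinal, inflammation and lipogenesis genes.

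**Figure D3:**
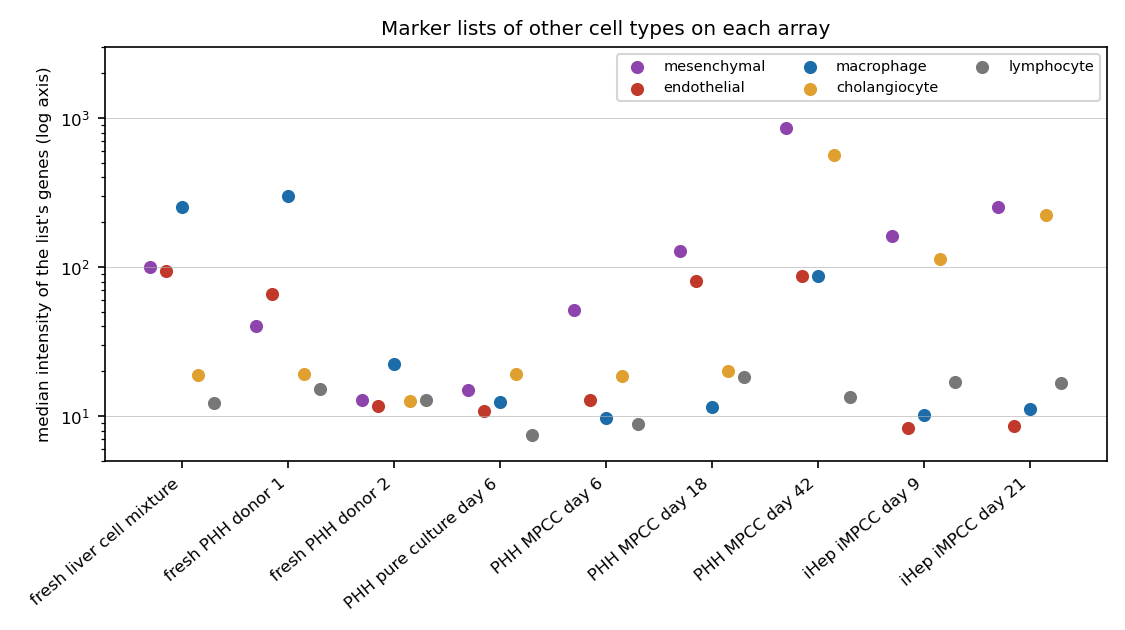
Median intensity of mesenchymal, endothelial, macrophage, cholangiocyte and lymphocyte marker lists on each of the 9 arrays, on a log axis.

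RNA of FABP1 and APOA2, which carry lipids, and of the mesenchymal genes PDGFRA and LOX was lower in pure culture at day 6 than in primary co-culture. FABP1, the liver fatty acid binding protein, was at 23.8 in pure culture and 3669 in co-culture (−6.53 ± 0.38 on the log2 scale, adjusted p = 0.0065). APOA2, a lipoprotein of HDL, was at 112 and 5169 (−5.28 ± 0.40, adjusted p = 0.0088). The protease ADAMTS1 (−6.02 ± 0.61), THRSP (−5.96 ± 0.66), PDGFRA (−5.31 ± 0.53) and LOX (−4.37 ± 0.51) completed the largest decreases. By its title pure culture held hepatocytes without supporting cells, and in co-culture the RNA of the 2 was not measured apart. ADAMTS1, PDGFRA and LOX were at 3.58, 3.92 and 13.6 in pure culture, and their decreases cannot be assigned to the hepatocytes. AHSG (fetuin A, −4.23 ± 0.27), F9 (−2.85 ± 0.32) and UGT2B4 (glucuronidation, −3.11 ± 0.33), whose probe set may detect related UGT2B genes, fell as well. HAMP rose most, from 65.1 to 1652 (4.37 ± 0.38, adjusted p = 0.0178), followed by the epithelial gene CRCT1 (4.04 ± 0.42), the natriuretic peptide receptor NPR3 (3.17 ± 0.23), GLIPR1 (2.82 ± 0.30), the peptide hormone gene CALCB (2.68 ± 0.25) and ABTB3 (2.62 ± 0.23). Large values without a call were CYP2C8 (−5.38, adjusted p = 0.154) and the urea cycle gene OTC (−4.50, adjusted p = 0.36). ALB was at −0.87 ± 0.23 (adjusted p = 0.374) and CYP3A4 at −0.45 ± 0.42 (adjusted p = 0.706). In limma 6 genes were higher and 12 lower (0.109%), all at least 2-fold. The 1 pure-culture array was assumed to vary like the other arrays, and every p-value of this comparison, list tests included, rests on that assumption. The iHep and fresh arrays enter this comparison only through the shared estimate of the spread. Without 1 or the other iHep array 0 were higher and 1 lower (1191 at an unadjusted p under 0.05 in limma). The counts were 2 and 5 without the co-culture day 18 array, and 82 were lower without the day 6 array. With donor as a block the counts were 2 and 15 for the donor of the titles and 0 and 1 for that of the individual tags (1329 at an unadjusted p under 0.05 in limma).

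Of 36 plasma proteins 3 fell in pure culture (19 adjusted over the list alone, median −1.31, adjusted p = 3.42e-17), APOA2 and AHSG among them. Of 23 coagulation genes 1 fell (10 adjusted over the list alone, median −1.47, adjusted p = 3.17e-10). Of 22 mesenchymal genes 2 fell (7 adjusted over the list alone, median −1.89, adjusted p = 2.45e-07). Complement (0 of 17, 5 adjusted over the list alone, median −1.17, adjusted p = 5.73e-08), cytochromes (0 of 14, 3 adjusted over the list alone, median −1.59, adjusted p = 2.90e-06) and transporters (0 of 18, 3 adjusted over the list alone, median −1.06, adjusted p = 1.67e-04) fell. Conjugating enzymes (1 of 19, 2 adjusted over the list alone, median −0.80, adjusted p = 2.07e-04), endothelial markers (0 of 22, 0 adjusted over the list alone, median −1.30, adjusted p = 5.20e-04) and cholesterol synthesis (0 of 17, 0 adjusted over the list alone, median −0.84, adjusted p = 5.72e-04) did so too. Bile acid (0 of 13, 0 adjusted over the list alone, median −1.57, adjusted p = 0.0024), fetal (0 of 15, 3 adjusted over the list alone, median −0.37, adjusted p = 0.0037) and lipogenesis genes (0 of 23, 1 adjusted over the list alone, median −0.81, adjusted p = 0.0048) fell, and metallothioneins rose (0 of 7, 0 adjusted over the list alone, median 0.42, adjusted p = 0.0104). These 13 lists had adjusted p = 0.631 with an estimated correlation. Urea cycle (0 of 26, 6 adjusted over the list alone, median −0.46, adjusted p = 0.0014, adjusted p = 0.742 with an estimated correlation) and fatty acid oxidation (0 of 19, 0 adjusted over the list alone, median −0.59, adjusted p = 0.0024, adjusted p = 0.674 with an estimated correlation) fell. Gluconeogenesis (0 of 14, 2 adjusted over the list alone, median −0.65, adjusted p = 0.0279, adjusted p = 0.787 with an estimated correlation) and proliferation (0 of 28, 0 adjusted over the list alone, median −0.36, adjusted p = 0.0174, adjusted p = 0.816 with an estimated correlation) fell too. With the co-culture arrays of day 18 and day 42 both left out, chosen after the data had been seen, endothelial markers had adjusted p = 0.521, and their median intensity was 10.9 in pure culture and 12.8 in co-culture at day 6. Proliferation did not pass with donor of the titles as a block (median −0.04, adjusted p = 0.442) or without the co-culture day 42 array (adjusted p = 0.796). Cytoskeleton genes rose with that block (median 0.62, adjusted p = 0.0037, against 0.175 without a block) and without the day 42 array (adjusted p = 5.07e-05). Without the co-culture day 6 array 7 calls ended, namely fatty acid oxidation (adjusted p = 0.0656), bile acid (0.108), cholesterol (0.057), gluconeogenesis (0.364), lipogenesis (0.174), metallothioneins (0.057) and urea cycle (0.174). Erythroid genes (median −0.26, adjusted p = 0.0525) fell with arrays centred (0.0466), with no filter (0.0243) and with a pseudocount of 1 (0.0385). After quantile normalization oxidative phosphorylation and cytoskeleton genes rose (both 0.0411). With the day 18 and day 42 arrays both left out, liver transcription factors (0.0084) and oxidative phosphorylation genes (0.0258) fell, and immediate early (0.037) and cytoskeleton genes (3.34e-09) rose. Lymphocyte genes had a median of −0.15, and of −0.51 with the stricter filter. Median and mean differed in sign for acute phase and oxidative phosphorylation genes. Since supporting cells were present only in co-culture, the lower mesenchymal, endothelial and fetal lists in pure culture cannot be assigned to the hepatocytes.

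At the same day and from the same donor by the titles, pure culture differed from co-culture at day 6 by at least 2-fold upward in 521 genes and downward in 668 (Spearman correlation 0.92). ANXA3 (a membrane-binding annexin, 5.13), HAMP (4.53), the differentiation inhibitor ID1 (4.46), CRCT1 (4.34) and the biliary keratin KRT7 (4.01) were higher. THRSP (−6.91), FABP1 (−6.59), APOA2 (−5.55), CYP2E1 (−5.41) and CYP2A7 (−5.33) were lower. Of cytochromes 11 of 14 were at least 2-fold lower (median −2.19), as were 13 of 18 transporters (−1.81), 11 of 13 bile acid genes (−1.81), 16 of 23 coagulation genes (−1.73), 23 of 36 plasma proteins (−1.51), 13 of 17 cholesterol genes (−1.29) and 12 of 23 lipogenesis genes (−1.20). Mesenchymal genes had a median of −0.55, and cytoskeleton genes 0.77, above all random lists. No test was made of this pair of single arrays.

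Between day 9 and day 21, the iHep arrays differed in few genes. At least 2-fold differences were seen for 153 genes upward and 149 downward (Spearman correlation 0.967). FSTL1 (2.81), the collagen gene COL1A1 (2.43), SPP1 (2.23), LUM (2.19) and HTRA1 (2.18) were higher at day 21. CYP1A1 (−2.84), TMEM65 (−2.42), DLK1 (−2.13), CXCL17 (−2.09) and the glucose-releasing G6PC1 (−2.01) were lower. On the probe sets used, the mesenchymal list had a median difference of 0.0087, with 2 of 22 genes at least 2-fold higher and 1 lower. That median depends on the choice of probe set. Other probe sets of COL1A2 (13.31 at day 9 and 135.29 at day 21 on 1 of them) and COL3A1 (7.85 and 52.28 on 1) read higher at day 21. Those of COL5A2 (596.25 and 586.56) and POSTN (36.94 and 32.22) did not, and that of FBN1 was dim on both arrays (2.98 and 4.74). Urea cycle and amino acid genes had a median of −0.76, with 10 of 26 at least 2-fold lower, below all 10000 random lists. Bile acid (−0.65), gluconeogenesis (−0.64), cholesterol (−0.63), lipogenesis (−0.60), coagulation (−0.54), plasma protein (−0.45), complement (−0.43) and fatty acid oxidation genes (−0.41) also lay below all of them. Above all random lists lay inflammation (0.67, with CXCL8 at 2.12), proliferation (0.62, with CDK1 at 1.45), metallothioneins (0.44) and cytoskeleton genes (0.26). ALB differed by 0.20, AFP by −0.29 and CYP3A4 by 0.33. The GAPDH 3-prime over 5-prime ratio (3.38 and 4.52) and the 18S ribosomal RNA probe sets (3282 and 4102) were also higher at day 21, alongside these list differences.

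In primary co-culture, day 18 exceeded day 6 by at least 2-fold for 622 genes and fell short for 327 (Spearman correlation 0.925), again from single arrays. The genes with the largest excess were FCN3 (a lectin of sinusoids, 4.83), DNASE1L3 (4.50), SPARC (4.06), CLEC1B (3.97) and GNG11 (3.92). Among them FCN3, DNASE1L3 and CLEC1B belong to the endothelial list. Lower at day 18 were IDI1 of sterol synthesis (−2.70), SLC38A7 (−2.59), LCN2 (−2.31), YAE1 (−2.23) and the serine synthesis enzyme PHGDH (−2.14). Endothelial (median 1.46) and mesenchymal markers (1.26), each with 13 of 22 genes at least 2-fold higher, and immediate early genes (0.61) lay above all random lists. Complement (−0.94), gluconeogenesis (−0.72), urea cycle (−0.58), conjugating enzymes (−0.56), liver transcription factors (−0.51), cholesterol (−0.47) and coagulation (−0.43) lay below all. The median endothelial intensity was 12.8 at day 6, 80.7 at day 18 and 86.6 at day 42.

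The fresh mixture of liver cells and fresh hepatocytes of donor 1 were close (Spearman correlation 0.969), with 56 genes at least 2-fold higher and 33 lower in the mixture. After quantile normalization the counts were 30 and 38. Higher were ZNF583 (1.67), the stromal collagen COL14A1 (1.55), HHIP (1.52), the growth factor HGF (1.44) and WFDC1 (1.36). Lower were the neutrophil genes S100A12 (−3.14), S100A8 (−2.61), S100A9 (−2.17) and MMP8 (−2.13) with CYP8B1 (−2.19), at 2401 in the mixture and at the top of the range in fresh hepatocytes (11029). Of 22 mesenchymal markers 9 were at least 2-fold higher (median 0.94, above all random lists). Macrophage markers had a median intensity of 252 in the mixture, 301 in fresh hepatocytes of donor 1 and 22.4 in those of donor 2.

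**Figure D4:**
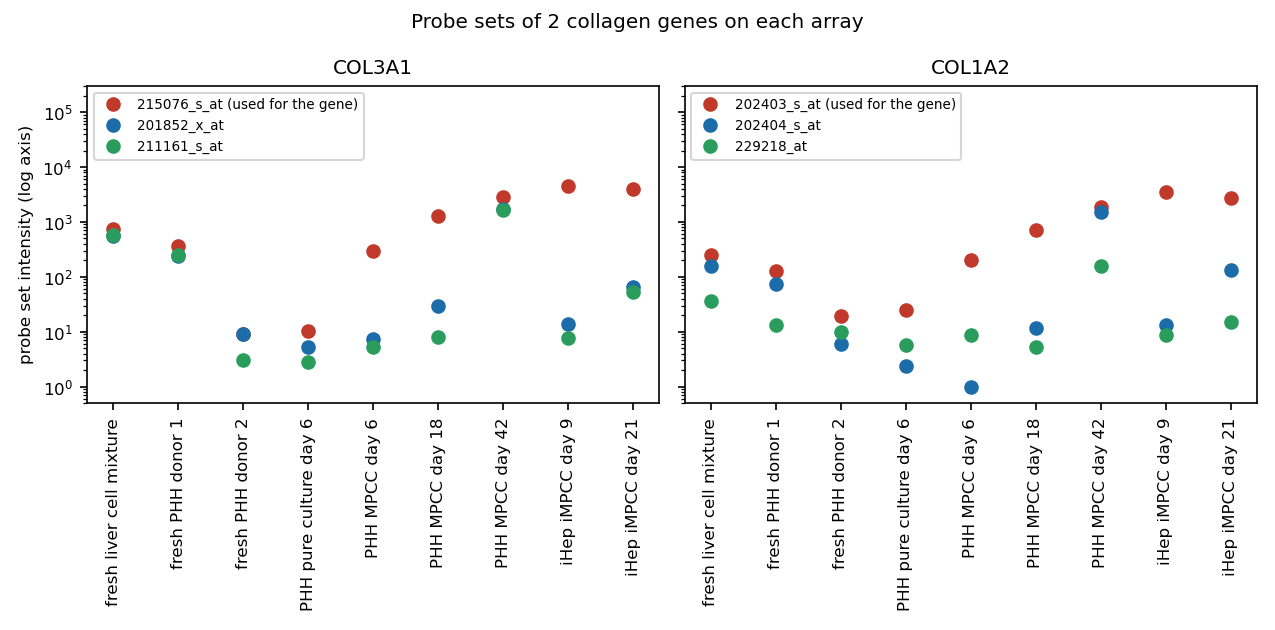
Intensity of each probe set of the collagen genes COL3A1 and COL1A2 on each array, on a log axis.

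Mesenchymal markers had a median intensity of 161 and 253 on the iHep arrays and 51.4, 128 and 855 in primary co-culture at days 6, 18 and 42. They were at 14.9 in pure culture, 40.6 and 12.9 in fresh hepatocytes and 100 in the mixture. Probe sets of the same collagen gene gave different readings. The COL3A1 probe set used here was at 4534 and 3904 in iHeps and 756 in the mixture, while the other probe sets of COL3A1 were at 14 and 66.5, and 7.85 and 52.3, in iHeps and at 545 and 569 in the mixture. For COL1A2 the readings in iHeps were 3505 and 2688 on 1 probe set, 13.3 and 135 on another and 8.81 and 15.1 on the last.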

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

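The test of mesenchymal genes on the iHep arrays was chosen after results had been seen, and all other tests in this part before. Control probe sets, which no comparison used, separated the iHep arrays from the primary arrays. The 3 probe sets of 18S ribosomal RNA were 25.2 times brighter on the iHep arrays (3282 to 4102 against 92.0 to 252), and the 12 probe sets of added poly-A spikes were brighter on the primary arrays (125 to 342 against 3.96 to 4.63). The size of the ratio of 46.9 is uncertain, since the iHep readings lay below the intensity of 16 taken as near background.

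The differences between iHeps and primary hepatocytes in genes such as CYP2E1 and AFP could come from cell source or from protocol, and no array breaks that tie. The mean GAPDH 3-prime over 5-prime ratio of the iHep arrays was 3.95. If labelling reach alone had lowered genes in iHeps against fresh hepatocytes, the other bright probe sets of those genes should have been near 0, but their median was −0.97, with 83.4% of 1034 below 0, between the values set for either reading. For genes higher in iHeps the median of 1752 other probe sets was 0.83, with 81.3% above 0, and this too left a kit effect open. Both tests used other probe sets chosen as bright on the arrays where the genes were higher. That choice pushes the medians away from 0, so neither test can exclude a protocol effect. A further test chose other probe sets by brightness on the fresh mixture. Genes higher in iHeps that were also higher in co-culture than in pure culture had a median of 0.0057 over 43 such probe sets. The remaining genes had 0.29, with 60.6% of 1508 probe sets above 0. Cross-hybridizing RNA of the support cells thus stayed open for the 83 genes also higher in co-culture, where 119 would be shared by independent lists. The genes higher in co-culture than in pure culture also include hepatocyte genes that were low in iHeps, such as THRSP (6.91) and CYP2E1 (5.41). The size of the overlap therefore does not measure support-cell RNA, and such RNA is not excluded for the remaining called genes.

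Catalase (CAT) and the methyltransferase BHMT2 were the 2 genes below an intensity of 16 on both iHep arrays and above 500 on every primary array. This held on the probe set used for each gene. The other bright CAT probe set was at 18.7 and 23.8 in iHeps and at 203 in pure culture. That of BHMT2 was at 4.43 and 3.89 in iHeps and at 490 in co-culture at day 42. CAT was at 10.3 and 9.64 against 607 to 4434, and BHMT2 at 14.1 and 8.64 against 529 to 2653. Of the 2 other bright probe sets, 100% were at least 4-fold lower as well (−4.13 for CAT and −5.67 for BHMT2). This argues against the failure of a single probe set. A loss shared by the probe sets of a gene, through the protocol, is not excluded. A hypothesis is that both genes may have been silenced in the stem cell state and were not switched on again, which DNA methylation of these cells could show and these arrays do not.

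Mesenchymal genes such as COL3A1 and POSTN were higher in co-culture, where cross-hybridizing RNA of supporting fibroblasts is a candidate explanation and human stromal cells are the biological alternative. At day 6, 0% of the 7 other probe sets that work on human mesenchymal RNA were at least 2-fold higher in co-culture than in pure culture, where cross-hybridization was predicted to put them. These 7 belong to 5 genes, and LOX, PDGFRA, COL6A3 and VIM had no other probe set, so the test does not reach them. The constant added before logs also damps changes near background. COL5A2 counted as not higher (0.77) at 20.27 in co-culture and 5.28 in pure culture. Those of FBN1 (27.51), POSTN (34.03) and 1 of COL1A2 (36.38) were dim in the mixture too, so the test cannot decide for them. COL3A1 was bright in the mixture (544.72 and 568.62) but at 7.41 and 5.31 in day 6 co-culture. The other COL1A2 probe set was at 159.12 and 1. On the iHep arrays 14.3% of the 7 were higher on both arrays but 57.1% on at least 1 of them, which leaves the explanation open there, with 1 COL1A2 probe set at 13.3 at day 9 and 135 at day 21. At day 42 the other probe sets of COL1A2 (1512), COL3A1 (1726 and 1674), COL5A2 (285) and POSTN (225) were bright, against 2.41, 5.25, 2.76, 5.28 and 27.8 in pure culture, so human stromal RNA could account for part of the rise on that array.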

How the results depend on the processing

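The setting without the day 18 and day 42 co-culture arrays was chosen after results had been seen, and all other settings before. The counts of iHeps against either primary group stayed within 1.5 times of the values given under every setting that kept all arrays. No list of these comparisons that was called in either fit changed direction. Centring on array medians and the stricter filter moved no count beyond that. A result was counted as kept if it stayed on its side of the threshold and did not turn direction where either fit called it. A turn between uncalled values was not counted as a change. Over all settings, named genes were kept in 1046 of 1241 results for iHeps against primary co-culture, 1114 of 1258 against fresh hepatocytes, 735 of 988 for co-culture against fresh hepatocytes and 792 of 930 for pure culture against co-culture. List results were kept in 509 of 543, 527 of 543, 556 of 607 and 584 of 607. Most named genes were picked as the largest called changes, and lists that stayed uncalled count as kept, so these shares run high. Of all genes called, the mean of all probe sets kept 2131 of 3265 for iHeps against primary co-culture. It kept 3166 of 4558 against fresh hepatocytes and 54 of 133 for co-culture against fresh hepatocytes. With arrays centred on their medians 3119, 4404 and 133 were kept. Dim genes near background and the number of arrays limit what can be called.

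Counts are given as higher and lower. For co-culture against fresh hepatocytes they were 12 and 32 with no filter, 14 and 52 with the mean of all probe sets, 12 and 49 with a pseudocount of 64, 5 and 11 with only the groups compared, 18 and 27 with donor of the titles as a block, and 0 and 0 in limma (2427 at an unadjusted p under 0.05) with donor of the individual tags. Quantile normalization gave 76 higher and a pseudocount of 1 gave 77. For pure culture against co-culture, 4 were lower with no filter, 12 higher with the mean of all probe sets and 11 higher with trend and robust options. The counts were 3 and 6 with a pseudocount of 1, 10 and 4 with 64, 0 and 1 with only the groups compared (1329 unadjusted in limma), 2 and 15 with donor of the titles as a block and 0 and 1 with donor of the individual tags.

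Single-array counts moved with the pseudocount and with the mean of all probe sets, and less with the filter on dim genes. With the mean of all probe sets they were 80 and 93 for iHep day 21 against day 9, 275 and 191 for co-culture day 18 against day 6, 333 higher for pure culture at day 6, and 25 and 20 for the mixture. With a pseudocount of 1 they were 622 and 576, 1545 and 1105, 1189 and 1709, and 588 and 572, and with 64 they were 49 and 69, 305 and 95, 241 and 405, and 7 and 11. Quantile normalization gave 30 higher in the mixture. A smaller pseudocount spreads dim genes by construction, and for the other settings the cause was not tested.

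With each array left out in turn, counts ranged from 122 to 2263 higher and 41 to 1405 lower for iHeps against co-culture, 805 to 3118 and 340 to 1685 against fresh hepatocytes, 0 to 562 and 1 to 276 for co-culture against fresh hepatocytes, and 0 to 9 and 1 to 82 for pure culture. Without the day 18 and day 42 co-culture arrays they were 1288 and 595, 2830 and 1419, 0 and 0 (1375 unadjusted in limma), and 0 and 0 (949 unadjusted).

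Few results reversed. For iHeps against fresh hepatocytes KLRD1 was at −0.14 after quantile normalization and −0.17 with a pseudocount of 1, IGHM at −0.39 with the mean of all probe sets and −1.19 with a pseudocount of 64, and with the mean of all probe sets MKI67 was at 0.22 and PLIN5 at 0.14. MKI67 was at 0.070 against co-culture with that mean. For pure culture, oxidative phosphorylation had a median of 0.21 after quantile normalization. For co-culture against fresh hepatocytes, conjugating enzymes had medians from −0.92 to −0.020 with each array left out in turn, the last without fresh hepatocytes of donor 2, where the test turned upward. Without the day 18 and day 42 arrays endothelial markers (−0.74) and proliferation (−0.32) turned in that comparison, and proliferation (0.093) in pure culture against co-culture. The cause was not tested.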

Other observations

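The genes in the first 2 paragraphs and the endothelial test were chosen after results had been seen. Genes of bile duct cells were bright on the primary co-culture array of day 42, and some of them on the iHep arrays. The duct keratin KRT19 was at 928 at day 42, 222 and 725 in iHeps at day 9 and day 21, and 2.74 to 17 on the other primary arrays. EPCAM was at 878 at day 42 and at 810 and 983 in iHeps, and SOX9, a transcription factor of duct and progenitor cells, at 577 and at 1234 and 1338. The water channel AQP1 (1436), the chloride channel CFTR (237) and the protease MMP7 (557) were bright at day 42 but at 24.0 and 21.5, 1.00 and 4.10, and 4.02 and 6.53 in iHeps. SPP1, a secreted duct protein, was at 5178 at day 42. The median of the cholangiocyte list was 567 at day 42, 114 and 224 in iHeps and 12.6 to 20.2 elsewhere.

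Among pluripotency genes, iHeps carried LIN28B (189 at day 9 and 130 at day 21) and SALL4 (69.9 and 74.1), which are also genes of fetal liver. The core factor NANOG was at 70.8 and 42.9 in iHeps and at 16.5 to 33.5 on the primary arrays. SOX2 was at 38.6 and 39.4, near its 37.2 in primary co-culture at day 18. The stem cell genes ZFP42 (2.96 and 1.89), UTF1 (12.5 and 11.7) and DPPA4 (13.5 and 13.6) lay below 16. The glycine-cleaving enzyme GLDC was at 1714 and 1202 in iHeps and 307 to 683 on the primary arrays.

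A hypothesis of human liver endothelial cells in the primary co-culture at day 18 was tested on the endothelial list. Of its 22 genes 13 were at least 2-fold higher than at day 6 (59.1%), FCN3, DNASE1L3 and CLEC1B among them, and 80% of the 5 other bright probe sets of these genes were too. The value set for this reading was above that, so the hypothesis stayed open, and a difference between preparations could also account for it.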
